A study of Mus musculus with 18 samples.

How the data were processed

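RNA from 18 samples of mouse lung and lung tumour was measured with an Affymetrix mouse 3' expression array, 1 colour and 1 array per sample. Samples were grouped by their titles, sources and group labels into control lung, spontaneous tumour and cobalt tumour, 6 each. Per the labels' protocols, tumours were dissected from the lung tissue around them and frozen, and 100 ng of total RNA was amplified and labelled for each array. The exposure to cobalt metal aerosol was by inhalation at 0 to 5 mg/m3, and male and female mice were in the study. The dose and the sex behind each sample are not given in the sources used here. The labels do not say that the arrays of a group come from separate animals, so p-values measure only the spread between these samples, which may in part be technical.

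The authors deposited log2 expression values made with RMA, per the submitters' processing notes. RMA in its usual form corrects the background, makes the distributions of the arrays alike and summarises the probes of a probe set by median polish. Its version and settings are not given in the sources used here. Quantile normalization of this kind assumes that most genes do not change and can hide a shift of all genes in one direction. Scanner files and detection calls were not used here, so the background of a dim probe set is unknown, and fold changes of dim probe sets can be too small in RMA values. Those of the brightest probe sets can be too small as well if the signal saturates, which was not tested. The deposited values ran from 3.34 to 15.26, with array medians of 6.32 to 6.45, and were used as they are, with no pseudocount. All 18 value columns were used.

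Of 45101 probe sets, 64 were control probe sets, 34945 had 1 gene symbol in the platform annotation, 932 had several and 9160 had none. Probe sets with several or no symbols were left out of the tests. Symbols were checked through their Entrez identifiers against a table of mouse RefSeq genes of assembly GRCm38.p6, used for names only: 34741 matched and 0 symbols changed. A gene was represented by the probe set with the highest mean over the 18 arrays, which left 18193 genes, 9010 of them with several probe sets. For arrays, the number of arrays limits the precision.

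The tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Each comparison was fitted in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, without trend or robust options), with 1 fit over all 18 arrays, group as the only factor, two-sided tests and Benjamini-Hochberg adjustment over the 18193 genes, at a threshold of 0.05. The submitters' design text compares each tumour group with the controls at that rate by another program, ORIOGEN, which was not run here. The comparison of the tumour groups with each other is not stated there and was added before the data were examined. The 36 gene lists, 18 of pathways and 18 of cell types, held 887 entries, of which 78 had no matching gene and were not analysed here. They were tested with camera at a preset correlation of 0.01, with adjustment over the 36 lists of a comparison, and again with an estimated correlation, and with fry. The correlation of fold changes between the tumour groups was set beside 100 simulations of unchanged groups against the same controls, and beside 20 divisions of the controls into 3 and 3.

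Named genes were, per comparison, the 10 largest log2 fold changes in each direction among genes past the threshold whose groups did not overlap and whose mean did not lie among the 6064 dimmest of 18193, or, with fewer than 5 in a direction, the 5 smallest p. For each list up to 2 members that rose and 2 that fell were eligible, or 4 each way for the NRF2, antioxidant, hypoxia and cell cycle lists, and not all eligible members are printed. Egfr, Nqo1, Hmox1, Gclc, Mki67, Sftpc, Ager, Scgb1a1 and Nkx2-1 were always named, and 2 further genes of that set were not analysed here. Clone names, Xist and Y-linked genes were left out of the largest changes. Genes outside this rule are said to have been chosen after their values were seen.

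Alternatives fixed in advance were cyclic loess normalization, leaving out the 6064 dimmest genes, the mean of all probe sets of a gene, eBayes with trend and robust options and array weights. Further ones were fitting only the 12 arrays of the groups compared, the replicate number as a block, the mean level of Y-linked RNA (3 of the 4 planned genes) as a covariate, each array left out in turn, an exact two-sided permutation test per gene over 924 assignments, and all probe sets in place of genes. Chosen after seeing the data were the arrays with an Xist level above 10 alone, leaving out control 1 and cobalt tumour 6 together, and an exact permutation test of each list's mean per array. The limma, permutation and list tests were tested on simulated data with 18193 genes. With 100 genes each changed by 1 and 2 log2 units, limma recovered 80% and 98% in a simulated comparison of cobalt tumours with controls and 79% and 96% in one of the tumour groups, with 7 false calls in each. The permutation test with adjustment recovered 0. A simulated comparison with no change gave 0 calls. The cell cycle list shifted by 0.5 gave a median of 0.516, and camera called 0 other lists. Simulated genes were drawn independently, with the same SD in every group. They therefore test neither the effect of correlated genes on camera nor that of unequal spread between groups on limma. Tables were prepared with Python 3.11.15 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.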

Results

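RNA levels were measured in the lungs of B6C3F1/N mice, a hybrid strain used in long-term carcinogenicity studies, by an Affymetrix oligonucleotide array hybridised to 18 samples. The mice belonged to an inhalation study of cobalt metal particles at 0 to 5 mg/m3 in the air, with exposure for 6 hours a day and 5 days a week for up to 105 weeks, per the labels' protocols. The tissues compared, with 6 arrays each, were lung of vehicle control mice (control lung), lung tumours that arose without cobalt (spontaneous tumours) and lung tumours of cobalt-exposed mice (cobalt tumours). Tumours were dissected from the surrounding lung before RNA extraction. The labels give neither the dose nor the sex of the mouse behind a sample, and they do not say that the arrays of a group came from separate mice, so p-values measure the spread between these arrays. The number of arrays limits the precision, and no other measure of depth applies to array values.

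Array medians lay between 6.32 and 6.45 on the log2 scale. The first principal component held 52.8% of the variance and separated the 6 control lungs, at -67.7 to -63.7, from 11 of the 12 tumours, at 17.0 to 60.6. Cobalt tumour 6 lay between them, at -24.5, and correlated more closely with the control lungs (mean r = 0.971 across probe sets) than with the other cobalt tumours (mean r = 0.953). Spontaneous tumours 2 and 6 stood apart from the other tumours on the second component (12.6% of the variance), at 62.1 and 53.5. Xist, the RNA that coats the inactive X chromosome of female cells, was high in all 6 control lungs (log2 12.15 to 12.72), in 2 of 6 spontaneous tumours and in 4 of 6 cobalt tumours. The remaining 6 tumours, spontaneous tumours 1, 2, 3 and 5 and cobalt tumours 1 and 4, had Xist levels of 5.95 to 6.82 and the Y-linked RNAs Kdm5d, Eif2s3y and Uty at 7.11 or more. Each tumour-against-control comparison therefore also sets tumours of both kinds against control lungs of 1 kind. Controls 5 and 6 were more alike than any other pair of controls (r = 0.9963, SD of the log2 difference 0.183, against 0.27 or more for the other pairs) but held different values and were counted as separate arrays. The free-text description of control 6 names a spontaneous tumour, whereas its title, source and group name a control. Its mean r was 0.989 with the other controls and 0.935 with the spontaneous tumours, and it was kept as a control.

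**Figure D1:**
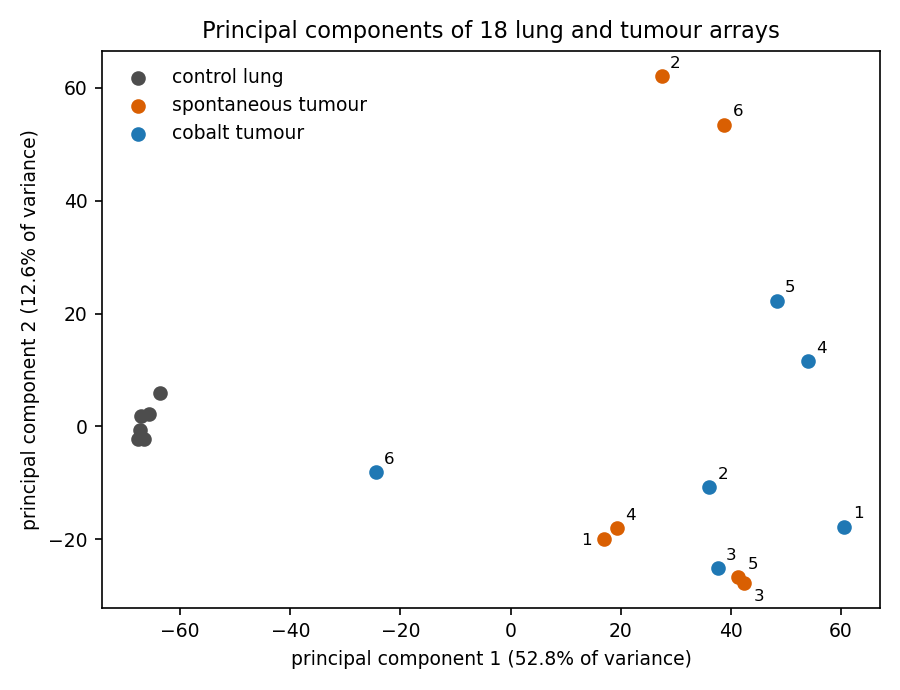
Principal components of the 18 arrays over 18193 genes, with 1 point per array coloured by group and tumours marked with their replicate number. Control lungs lie at -67.7 to -63.7 on component 1, cobalt tumour 6 at -24.5 and the other tumours at 17.0 or more.

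The first comparison asked how spontaneous tumours differed from control lung. Cldn2, a claudin of epithelial tight junctions, rose 58.6-fold, from a log2 level of 5.44 ± 0.30 in control lung to 11.32 ± 0.97 in spontaneous tumours (SD, n = 6 each). The macrophage elastase Mmp12 rose 31.9-fold, the arginase Arg1 30.7-fold and the HIF prolyl hydroxylase Egln3 17.6-fold, and Tc2n, Kng1, Sertad4, S100a14, Klk13 and Inava rose 12.6-fold to 17.2-fold. Losses of like size were seen for the endothelial membrane protein Tmem100 (44.7-fold lower, 12.42 ± 0.31 in control lung against 6.93 ± 1.58), the prostaglandin-degrading enzyme Hpgd (29.5-fold lower) and the paraoxonase Pon1 (32.6-fold lower). Also lower were the matrix genes Pcolce2 (33.8-fold lower) and Ogn (30.5-fold lower), Mapt (29.4-fold lower) and Gpm6a (27.3-fold lower). The heart muscle genes Actc1, Myl7 and Myh6, which are also expressed in the muscle sleeve of mouse pulmonary veins, were 29.0-fold to 31.8-fold lower. In each of these 20 genes every tumour lay beyond every control, as the rule for naming them required, with limma adjusted p of 0.000549 or less. Across 18193 genes, limma with Benjamini-Hochberg adjustment called 2975 genes higher and 3320 lower at a false discovery rate of 0.05, which was 34.6% of genes. Of them, 755 and 1226 differed at least 2-fold.

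Genes of the oxidative stress response moved in both directions in spontaneous tumours. Each array measured the RNA of all cells in a sample, and many markers of normal lung cells fell in tumours, as described below. These counts therefore do not tell a change within tumour cells from a loss of normal lung cells. Of 30 measured targets of NRF2, the transcription factor that answers to oxidants, 9 rose, 4 fell and 17 did not pass the test, with 9 and 4 when adjusted over the list alone. The aldo-keto reductase Akr1b8 rose 5.25-fold, malic enzyme Me1 4.74-fold, the efflux pump Abcc4 3.5-fold, haem oxygenase Hmox1 3.14-fold (log2 8 ± 0.21 to 9.65 ± 0.75) and Gclc, the catalytic subunit for glutathione synthesis, 2.27-fold. The quinone reductase Nqo1 was 2.17-fold lower and the glutathione transferase Gstm1 2.25-fold lower. Nqo1 was dim, at 5.94 to 6.93 in control lungs and 5.01 to 5.50 in spontaneous tumours, where array medians were 6.32 to 6.45. Whether it was detected is unknown, since no detection calls were used. The list's median log2 change was 0.35, with a camera adjusted p of 0.0236 and an adjusted p = 0.351 with an estimated correlation. Its adjusted p was 0.161 (median 0.23) after cyclic loess normalization and 0.0678 without the 6064 dimmest genes, and its median was 0.22 without spontaneous tumour 2 and 0.23 without spontaneous tumour 6. Fry gave the list an adjusted p of 0.00434. The exact permutation of its mean per array, added after the camera results were seen, gave 0.03. Camera's call was kept in all 18 fits that left out 1 array. Among 28 other antioxidant enzymes, 6 rose and 4 fell, the same numbers as when adjusted over the list alone. The glutaredoxin Glrx rose 2.99-fold and the peroxiredoxins Prdx4, Prdx2 and Prdx3 rose 2.54-fold, 2.27-fold and 1.97-fold, while extracellular superoxide dismutase Sod3 was 8.89-fold and the secreted peroxidase Gpx3 6.11-fold lower. Their median log2 change was 0.12 and their mean -0.02, opposite in sign. Camera gave an adjusted p of 0.285, while fry gave 0.0395 and cyclic loess moved the median to -0.01. Of 12 genes for enzymes that make reactive oxygen, 2 rose and 1 fell (adjusted p = 0.785 by camera). The NADPH oxidase organiser Noxo1 was 5.2-fold higher and the oxidase Nox4 8.89-fold lower, and camera's direction was up although the median was -0.02. Of 17 genes of the response to metals 4 rose, among them the metallothionein Mt2 (4.33-fold), and 4 fell, among them the hepcidin gene Hamp (7.36-fold lower). Their median was 0.06 and the adjusted p 0.629. The unfolded protein and integrated stress response list had 5 risers, led by the serine synthesis enzyme Psat1 (3.54-fold), and 2 that fell among 26 (adjusted p = 0.28).

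Most cell cycle and hypoxia genes rose in spontaneous tumours, and a smaller part of the genes of other tumour programmes did. In the cell cycle list 33 of 39 genes rose and none fell (34 and 0 when adjusted over the list alone), with a median log2 change of 1.21 (camera adjusted p = 4.25e-13, and adjusted p = 0.345 with an estimated correlation). Rrm2, Ect2, Birc5 and Cenpf, which act in DNA synthesis and in mitosis, rose 5.12-fold, 4.31-fold, 4.23-fold and 4.13-fold, and the proliferation marker Mki67 rose 3.48-fold (7.20 ± 0.52 to 9 ± 0.47). Of 31 hypoxia and HIF targets 20 rose and 1 fell (median 0.97, adjusted p = 6.06e-08, and adjusted p = 0.33 with an estimated correlation). The glycolytic enzymes Hk2 (4.41-fold) and Tpi1 (4.22-fold) were among the risers, while the angiogenic factor Vegfa was 1.9-fold lower. Of 22 genes induced by MAPK signalling 10 rose and none fell (median 0.78, adjusted p = 0.000161, and adjusted p = 0.345 with an estimated correlation), led by the EGF receptor ligand Ereg (11-fold) and the phosphatase Dusp4 (8.18-fold). Lipid and sterol synthesis genes (9 rose, 2 fell of 23, median 0.37) had a camera adjusted p of 0.00428 and gastric and gut epithelial genes (7 rose, 1 fell of 25, median 1.10) one of 0.00317. For injury-associated epithelial genes (9 rose, 1 fell of 23, median 0.98) it was 0.000226 and for DNA repair genes (9 rose, 0 fell of 26, median 0.14) 0.00156. With an estimated correlation each of these 4 lists had an adjusted p = 0.345. On the injury-associated list spontaneous tumours 2 and 6 lay 2.44 and 2.03 log2 above the control mean and the other 4 lay 0.18 to 0.61 above it, and without spontaneous tumour 2 the median was 0.53 (adjusted p = 0.00263). The gastric and gut median was 0.70 without spontaneous tumour 1 and 0.67 without spontaneous tumour 6. As fixed in advance, that list also held Meg3, an imprinted noncoding RNA that rose by 3.62 log2, and Clu, which was on the injury-associated list too. Neither is particular to the gut, and the list was not tested without them in any comparison. The strongest risers of these 4 lists were the fatty acid binding protein Fabp5 (5.68-fold), the aspartic protease Ctse (15.1-fold), the secreted chaperone Clu (6.26-fold) and Nudt1, which removes oxidised nucleotides (2.39-fold). Ctse was at 6.74 in spontaneous tumour 1, within the 5.73 to 7.07 of the control lungs, and at 8.89 to 13.18 in the other spontaneous tumours. Of 25 p53 targets 9 rose and 3 fell (median 0.28, camera adjusted p = 0.0283, adjusted p = 0.345 with an estimated correlation), with Ccng1 2.68-fold higher and Fas 3.02-fold and Sesn1 2.88-fold lower. Without spontaneous tumour 2 the list's adjusted p was 0.0669 (median 0.22), and it was 0.0888 with cyclic loess, 0.181 without the 6064 dimmest genes and 0.0544 with array weights.

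Markers of the normal lung's vessels, ciliated airway cells and muscle fell, while those of macrophages rose and those of alveolar type 2 cells lay above all controls in 4 of 6 tumours. All 25 ciliated cell markers fell (median log2 change -2.17, camera adjusted p = 3.74e-16), as did 28 of 31 endothelial markers (median -2.58, 3.88e-17), 17 of 19 heart muscle genes (median -2.97, 6.33e-15) and 15 of 18 smooth muscle and pericyte markers (median -1.52, 3.58e-08). With an estimated correlation the adjusted p was 0.33 for ciliated, endothelial and smooth muscle markers and 0.187 for heart muscle. Examples were the microtubule protein Tppp3 (12.2-fold lower), the tight junction protein Cldn5 of endothelium (fell by 3.94 on the log2 scale) and the calponin Cnn1 of smooth muscle (10.0-fold lower), while the pericyte regulator Rgs5 rose 12.2-fold. Of 29 fibroblast and matrix genes 17 fell and 2 rose (median -0.95, 0.000135, and adjusted p = 0.345 with an estimated correlation), with the fibroblast transcription factor Tcf21 26.4-fold lower and the collagen Col1a1 2.05-fold higher. Of the mesothelial markers 8 of 13 fell (median -1.12, 0.00741, and adjusted p = 0.351 with an estimated correlation), but without the 6064 dimmest genes the list missed the threshold (median -0.06, 0.167). Of 22 alveolar type 1 markers 14 fell and 1 rose (median -1.46, 0.000196, and adjusted p = 0.345 with an estimated correlation), with Ager, the receptor abundant on these cells, 2.21-fold lower. Ager lay at 14.46 to 14.58 in control lungs, near the highest value of the data (15.26), so its fold may be too small. Of 23 xenobiotic metabolism genes 13 fell (median -1.60, 0.000638, and adjusted p = 0.345 with an estimated correlation), with Cyp4b1 17.8-fold lower. Alveolar type 2 markers had 10 risers and none that fell among 22 (median 0.57, 0.000412, and adjusted p = 0.425 with an estimated correlation), led by the cathepsin Ctsh (3.8-fold). Their mean level was 1.06 to 1.33 log2 above the control mean in 4 tumours and -0.31 and -0.44 relative to it in spontaneous tumours 2 and 6, below every control. An exact permutation test of that mean, added after the camera results were seen, gave an adjusted p of 0.0752, and the median was 0.86 without spontaneous tumour 2 and 0.88 without spontaneous tumour 6. Surfactant protein Sftpc was at 14.98 ± 0.40 in tumours and 14.91 ± 0.05 in control lung (limma adjusted p = 0.726), near the highest value of the data (15.26), where a difference may not be measurable. The lung lineage factor Nkx2-1 differed by 0.37 log2 (0.268). Among 19 club cell markers 7 fell and 4 rose (median -1, camera adjusted p = 0.147), with the airway secretory protein Bpifa1 68.3-fold higher and Cyp4b1, which is on this list too, lower. Bpifa1 overlapped between the groups, at 4.66 to 8.99 in control lungs and 8.57 to 14.72 in spontaneous tumours. Fry gave the club cell list an adjusted p of 0.0199 and the exact permutation of its mean 0.0213, with 5 of 6 tumours below all controls on that mean. Scgb1a1, the main club cell secretory protein, was at 13.97 ± 0.83 against 14.97 ± 0.10 (adjusted p = 0.318), which is near that highest value too.

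Immune cell markers of spontaneous tumours also moved in both directions. Of 21 alveolar macrophage markers 10 rose and none fell (median log2 change 1.04, camera adjusted p = 0.000249, and adjusted p = 0.345 with an estimated correlation), with the nuclear receptor Pparg 4.28-fold higher. Of 24 markers of other macrophages and monocytes 13 rose and 3 fell (median 0.72, 0.000638, and adjusted p = 0.345 with an estimated correlation), with Lyve1 6.04-fold lower. Of 26 T and NK cell markers 12 fell and none rose (median -0.43, 0.000638, and adjusted p = 0.351 with an estimated correlation), with the granzyme Gzma 6.03-fold lower. Markers of red cells and platelets (5 of 10 fell, median -0.61, 0.0269) and of adipocytes (4 of 8 fell, median -0.56, 0.0236) were lower, with the haem synthesis enzyme Alas2 14.8-fold and the lipase Lipe 4.11-fold lower. With an estimated correlation both had an adjusted p = 0.345. In the arrays with high Xist alone 6 of the 27 lists called by camera in spontaneous tumours missed the threshold, and 1 list not called before passed. Among the 6 were red cells and platelets (adjusted p = 0.107) and adipocytes (0.0954). With array weights the adjusted p was 0.12 for red cells and platelets. The calls of 4 further lists hung on single arrays or on the test. Of 31 cytokines and chemokines 9 rose and 5 fell (median 0.32, camera adjusted p = 0.0378, and 0.477 with an estimated correlation), with Cxcl3 15-fold higher and Cxcl12 7.27-fold lower. That adjusted p was 0.0506 without control 2, 0.0529 without control 3 and 0.156 without spontaneous tumour 2. The list's median lay between 0.20 and 0.40 over the fits that left out 1 array. Interferon response genes (0 rose, 9 fell of 23, median -0.68) had an adjusted p of 0.0236, which was 0.07 without spontaneous tumour 5 and 0.536 with an estimated correlation. Mesenchymal transition regulators (3 rose, 7 fell of 19, median -0.56), with Zeb1 4.53-fold lower, had a camera adjusted p of 0.0355, which was 0.0501 without control 5, 0.0896 without spontaneous tumour 5 and 0.425 with an estimated correlation. B and plasma cell markers (0 rose, 6 fell of 23, median -0.56, 0.0392, and 0.536 with an estimated correlation) missed the threshold without any 1 of controls 3 and 4, spontaneous tumours 2, 3, 4 and 5 and cobalt tumour 6, at 0.0551 to 0.109. Their median lay between -0.87 and -0.40 over the fits that left out 1 array. Fry gave adjusted p of 0.0901 for cytokines and chemokines, 0.0549 for interferon response genes and 0.0577 for B and plasma cells, and the exact permutation of list means 0.0501 for interferon response genes and 0.118 for B and plasma cells. Without the 6064 dimmest genes the adjusted p was 0.534 for cytokines and chemokines, and with the Y-linked covariate it was 0.136 for interferon response genes and 0.166 for mesenchymal transition regulators and for B and plasma cells. Antigen presentation (0 rose, 8 fell of 20, median -0.41) had an adjusted p of 0.0699, which lay between 0.0212 and 0.0442 without control 1, spontaneous tumour 1 or 3 or cobalt tumour 5 and was 0.342 without spontaneous tumour 6 (median -0.19). Neutrophil markers (2 rose, 0 fell of 19) had an adjusted p of 0.8, with control 1 at 3.67 log2 above the control mean. Markers of dendritic cells, mast cells and eosinophils (3 rose, 5 fell of 24, with the mast cell receptor Kit 8.95-fold lower) and nerve, Schwann and neuroendocrine markers (0 rose, 2 fell of 13) had adjusted p of 0.21 and 0.202, and 0.00563 and 0.0166 with fry. Adjusted over the list alone, the numbers that rose or fell differed from those given by at most 3 genes in every list. Egfr, the epidermal growth factor receptor, was 1.38-fold lower (0.0371) and missed the threshold without any 1 of controls 2, 4, 5 and 6 and spontaneous tumours 1 to 5, at 0.0519 to 0.0906.

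**Figure D2:**
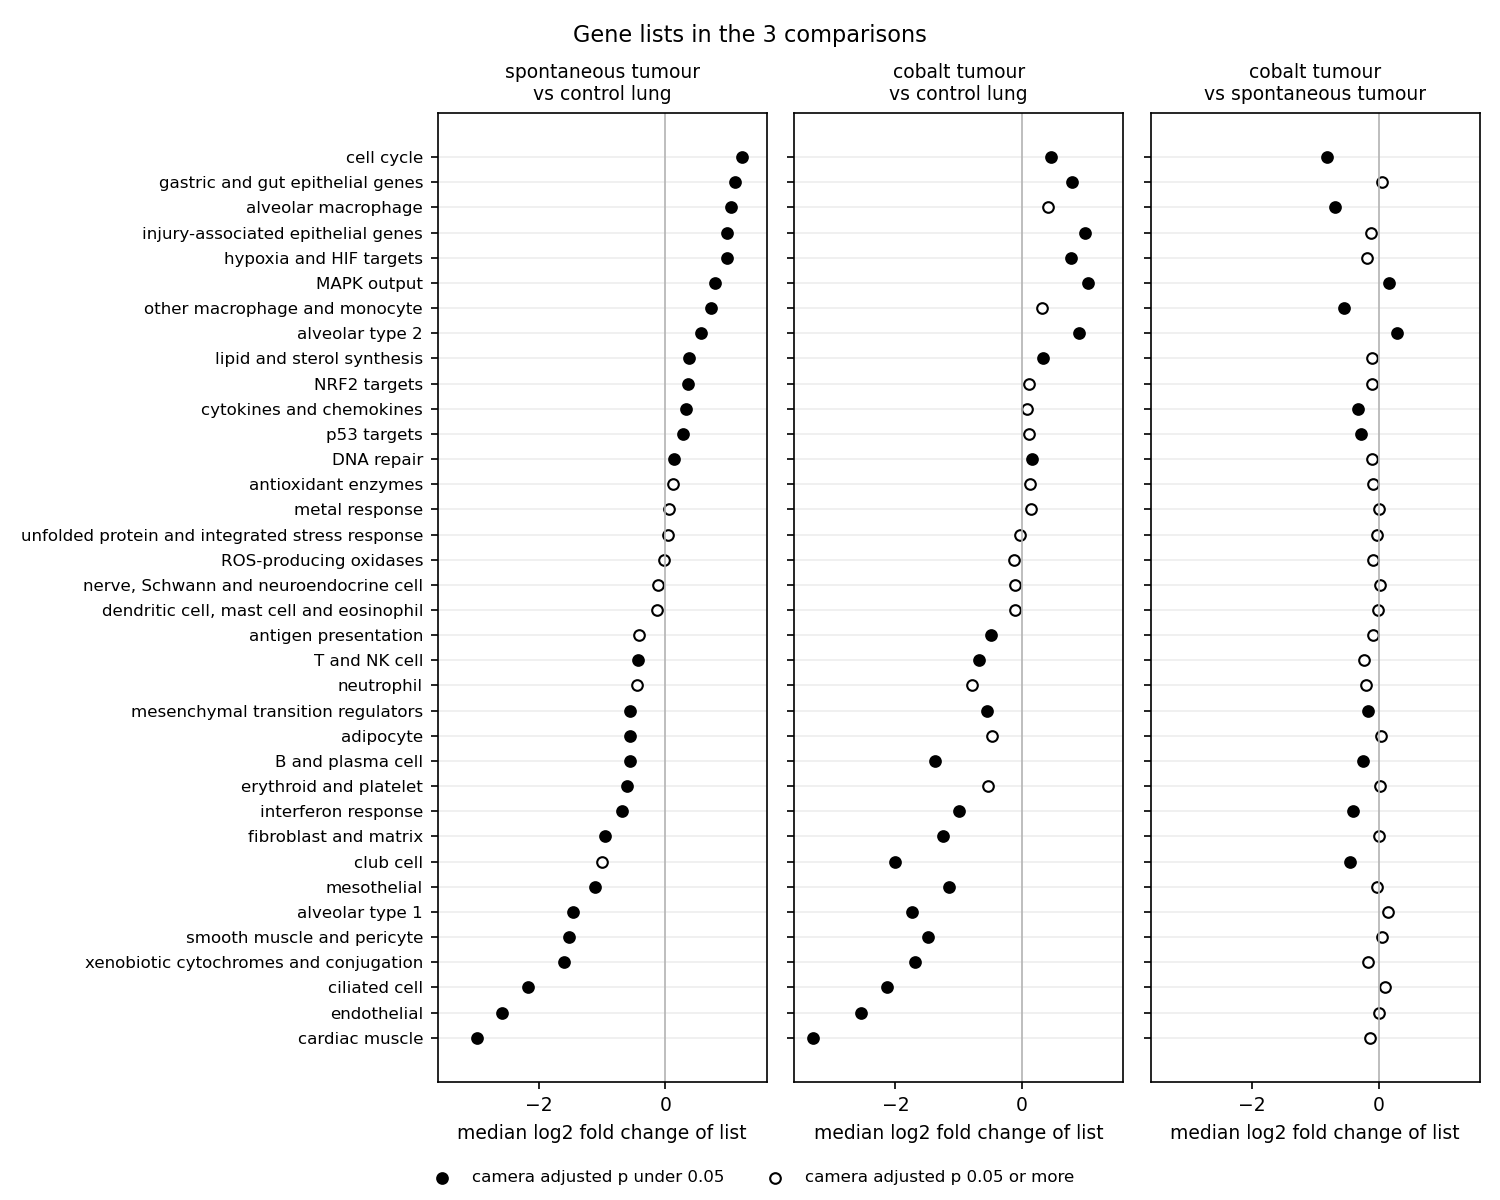
Median log2 fold change of the 36 gene lists (vertical axis) in each of the 3 comparisons, with filled points for a camera adjusted p under 0.05 at the preset correlation and open points otherwise. Medians of the endothelial list were -2.58 and -2.55 against control lung and 0.00 between the tumour groups.

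The second comparison asked how tumours of cobalt-exposed mice differed from the same control lungs. Gkn2, a gastrokine normally made by the stomach's surface epithelium, rose 258-fold, from a log2 level of 6.18 ± 0.41 in control lung to 14.19 ± 0.62 in cobalt tumours (SD, n = 6 each). Cobalt tumours reached 14.99, near the highest value of the data (15.26), so this fold may be too small. The granzyme Gzme rose 43.8-fold, Cldn2 39.5-fold, the kininogen Kng1 31.4-fold, the fetal serum protein Afp 29.2-fold and Ereg 28.9-fold, and Rian, an imprinted noncoding RNA, S100a14, Sertad4 and Tc2n rose 17.2-fold to 29.5-fold. Hpgd (58.4-fold), the heart muscle genes Actc1 (49.9-fold), Myl7 (49.1-fold), Myl4 (32.2-fold) and Myh6 (32.1-fold), Tmem100 (44.2-fold), the platelet chemokine Ppbp (32.8-fold), Gpm6a (29.5-fold), Pcolce2 (27.5-fold) and Tmcc2 (27.0-fold) were lower in cobalt tumours. By the same rule every tumour lay beyond every control in each of these 20 genes, with limma adjusted p of 0.000958 or less. Across all genes limma called 2679 higher and 3504 lower at a false discovery rate of 0.05, which was 34% of genes. Of them, 736 and 1363 differed at least 2-fold. Without cobalt tumour 6, the array nearest to the controls, 3014 genes were higher and 3749 lower, and 96.2% of the calls from all arrays were made again in the same direction.

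NRF2 targets and antioxidant enzymes divided in cobalt tumours as well, and neither list passed camera's test. Here too a change within tumour cells cannot be told apart from a loss of normal lung cells. Of 30 NRF2 targets 9 rose, 7 fell and 14 did not pass the test, with 9 and 7 when adjusted over the list alone. Akr1b8 rose 5.38-fold, Hmox1 3.31-fold (8 ± 0.21 to 9.72 ± 0.39), Me1 3.01-fold, Abcc4 2.71-fold and Gclc 2.31-fold, while the glutathione transferase Gsta2 was 4.73-fold, the epoxide hydrolase Ephx1 2.81-fold and Nqo1 1.76-fold lower. Nqo1 was dim here too, at 4.89 to 6.58 in cobalt tumours. The list's median log2 change was 0.11 (camera adjusted p = 0.0875, and 0.505 with an estimated correlation), and without cobalt tumour 3 it was 0.16 with an adjusted p of 0.0415, while fry gave 0.0477. Of 28 antioxidant enzymes 8 rose and 7 fell, also when adjusted over the list alone, with Glrx 4.62-fold and the paraoxonase Pon2 2.19-fold higher and Sod3 9.52-fold and Gpx3 4.06-fold lower. Their median was 0.13 and their mean -0.07, opposite in sign, with a camera adjusted p of 0.479. Of 12 oxidase genes 1 rose, Noxo1 (5.13-fold), and 2 fell, among them Nox4 (5.72-fold lower), with an adjusted p of 0.628. The metal response list had 5 risers, among them the iron exporter Slc40a1 (4.05-fold), and 5 that fell, among them Hamp (8.07-fold lower), in 17 (adjusted p = 0.875). The unfolded protein and integrated stress response list had 5 and 3 in 26 (0.572), where the median was -0.03 and camera's direction up.

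**Figure D3:**
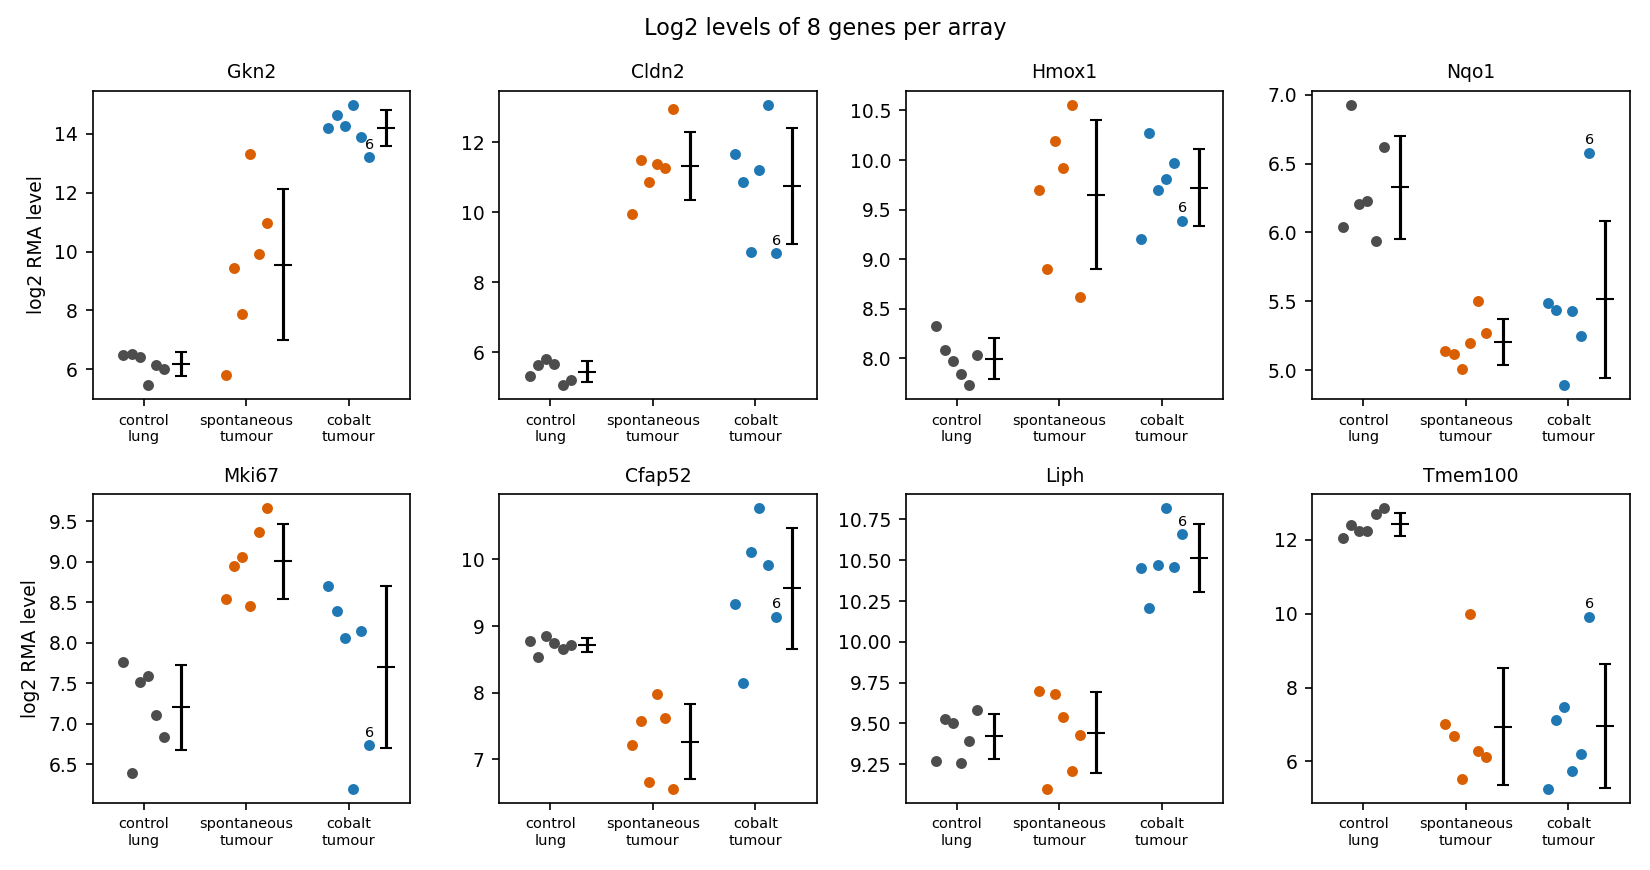
Log2 levels of 8 genes on each array, by group, with the bar and whiskers giving the mean and SD of 6 arrays and a 6 marking cobalt tumour 6. Gkn2 lay at 13.20 to 14.99 in cobalt tumours and at 5.82 to 13.31 in spontaneous tumours.

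Genes of MAPK output, hypoxia and alveolar type 2 cells rose in cobalt tumours. Of 22 MAPK-induced genes 14 rose and none fell (median log2 change 1.04, camera adjusted p = 9.32e-07, and adjusted p = 0.301 with an estimated correlation), with Dusp4 7.09-fold higher beside Ereg. Of 31 hypoxia and HIF targets 17 rose and 1 fell (median 0.78, 4.95e-06, and adjusted p = 0.407 with an estimated correlation), with Egln3 7.58-fold, Hk2 5.96-fold and the histone demethylase Kdm3a 4.72-fold higher and Vegfa 2.01-fold lower. Alveolar type 2 markers had 13 risers and 2 that fell in 22 (median 0.90, 8.35e-06, and adjusted p = 0.407 with an estimated correlation), with Ctsh 5.29-fold and the transcription factor Cebpa 4.06-fold higher. Sftpc was at 15.12 ± 0.07 (limma adjusted p = 0.244), again near the highest value of the data. Gastric and gut epithelial genes (8 rose, 0 fell of 25, median 0.79, 0.000721), injury-associated epithelial genes (11 rose, 3 fell of 23, median 0.99, 0.00063) and DNA repair genes (6 rose, 0 fell of 26, median 0.16, 0.013) passed too, with Ctse 12.3-fold, Cldn4 6.47-fold and Msh6 1.98-fold higher. With an estimated correlation the adjusted p of these 3 lists was 0.366, 0.407 and 0.411. In the cell cycle list 7 of 39 genes rose and none fell, with 1 riser when adjusted over the list alone (median 0.46, camera adjusted p = 0.000507, and 0.505 with an estimated correlation). Fry gave that list an adjusted p of 0.127 and the exact permutation of its mean per array 0.1, and without cobalt tumour 1 its median was 0.29. Its mean lay at -0.24 and -0.34 relative to the control mean in cobalt tumours 4 and 6 and at 0.65 to 1.17 in the other 4. The helicase subunit Mcm7 rose 2.15-fold, and Mki67 was at 7.71 ± 1.00 against 7.20 ± 0.52 (limma adjusted p = 0.339). Lipid and sterol synthesis genes had 7 risers in 23, with Fabp5 7.12-fold higher (median 0.33, 0.00445, and 0.407 with an estimated correlation), and missed the threshold without cobalt tumour 6 (median 0.23, 0.0592). DNA repair genes missed it without the 6064 dimmest genes (0.0541). Of 25 p53 targets 6 rose and 5 fell (median 0.11, adjusted p = 0.333), with Sesn1 3.1-fold lower.

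The normal tissue markers that fell in spontaneous tumours were also low in cobalt tumours. Markers of endothelium (30 of 31 fell, median log2 change -2.55, camera adjusted p = 1.73e-17), ciliated cells (24 of 25, -2.14, 6.41e-14), heart muscle (17 of 19, -3.31, 1.32e-15) and smooth muscle and pericytes (15 of 18, with 1 riser, -1.49, 6.65e-08) were lower. With an estimated correlation the adjusted p was 0.331, 0.366, 0.153 and 0.301. Of their members Cldn5 was 16.1-fold, Tppp3 12.5-fold and Cnn1 12.4-fold lower and Rgs5 14.5-fold higher. The same was so for fibroblast and matrix genes (18 of 29, -1.24, 1.35e-05), mesothelial markers (8 of 13, -1.15, 0.00375) and alveolar type 1 markers (15 of 22, with 1 riser, -1.74, 0.000844), each with an adjusted p = 0.407 with an estimated correlation. It was also so for xenobiotic metabolism genes (14 of 23, with 1 riser, -1.69, 0.000917, and adjusted p = 0.407 with an estimated correlation). Club cell markers were lower too (11 of 19 fell, with 3 risers, -2.01, 0.0185, and adjusted p = 0.407 with an estimated correlation). In spontaneous tumours they had missed the threshold with camera but not with fry or the exact permutation of their mean. The matrix protein Mfap4 was 25.8-fold, the club cell carbonyl reductase Cbr2 20.2-fold and Cyp4b1 24.4-fold lower. Cbr2 lay at 14.49 to 14.58 in control lungs, near the highest value of the data (15.26), so its fold may be too small. Of the immune lists, T and NK cell markers (18 of 26 fell, -0.68, 3.96e-05), B and plasma cell markers (12 of 23 fell, -1.37, 0.000682) and interferon response genes (14 of 23 fell and 1 rose, -0.99, 9.08e-05) fell, each with an adjusted p = 0.407 with an estimated correlation. The B cell antigen Ms4a1 was 9.47-fold, Gzma 7.42-fold and the interferon-induced Oasl2 5.1-fold lower. Mesenchymal transition regulators fell as well (12 of 19, with 1 riser, -0.56, 0.00149, and adjusted p = 0.407 with an estimated correlation). Without the 6064 dimmest genes the mesothelial markers missed the threshold (median -0.31, 0.105). In the arrays with high Xist alone 1 list called in cobalt tumours missed it and 2 not called before passed. Cobalt tumour 6 stood above the other cobalt tumours on several of these lists: its mean log2 level relative to control lung was -0.54 for ciliated markers, against -2.76 to -2.27 in the other 5. Antigen presentation genes (9 of 20 fell, -0.49, adjusted p = 0.0265, and 0.505 with an estimated correlation) missed the threshold without cobalt tumour 4 (0.0577) or 6 (0.0578).

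Other lists did not pass camera's test in cobalt tumours. Alveolar macrophage markers (4 rose, 2 fell of 21, median log2 change 0.41) had an adjusted p of 0.118, which was 0.0372 without cobalt tumour 1. For markers of other macrophages and monocytes (11 rose, 5 fell of 24, median 0.32, 0.0834) it was 0.017 without control 1, 0.0254 without control 4 and 0.0372 without cobalt tumour 1, and Mmp12 rose 13.0-fold and Arg1 7.76-fold. Markers of red cells and platelets (1 rose, 5 fell of 10, -0.54, 0.0663) passed without control 3 (0.0302) or 6 (0.0402), and adipocyte markers (3 of 8 fell, -0.48, 0.0552) without control 1, 3, 4, 5 or 6, spontaneous tumour 6 or cobalt tumour 6 (0.0314 to 0.0496), while without control 2 their median was -0.19 (0.185). Cytokines and chemokines (3 rose, 4 fell of 31), neutrophil markers (2 rose of 19), markers of dendritic cells, mast cells and eosinophils (1 rose, 4 fell of 24) and nerve, Schwann and neuroendocrine markers (1 of 13 fell) had adjusted p of 0.662, 0.662, 0.127 and 0.617. Fry gave 0.00181 for red cells and platelets and 0.00217 each for adipocytes and for dendritic cells, mast cells and eosinophils. Adjusted over the list alone, the numbers that rose or fell in cobalt tumours differed by at most 3 genes in every list except the cell cycle (7 and 1 rose) and B and plasma cells (12 and 17 fell). Egfr was 1.4-fold lower (limma adjusted p = 0.0295) but missed the threshold without control 2, 5 or 6 or cobalt tumour 2 or 5, at 0.054 to 0.0645. Scgb1a1 passed as lower (0.0438), with 9.97 and 10.27 log2 in cobalt tumours 1 and 4 and 14.17 to 14.97 in the other 4. The controls (14.84 to 15.05) lay near the highest value of the data, so its fold is not given here. It missed the threshold without any 1 of the 6 controls, spontaneous tumour 5 or cobalt tumour 1 or 4, at 0.0507 to 0.108. Ager (-0.61 log2, 0.0909) passed without spontaneous tumour 2 (0.0208) or cobalt tumour 6 (0.0486), and Nkx2-1 (0.62 log2, 0.0657) without spontaneous tumour 2, 3 or 6 or cobalt tumour 6, at 0.0363 to 0.0437.

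**Figure D4:**
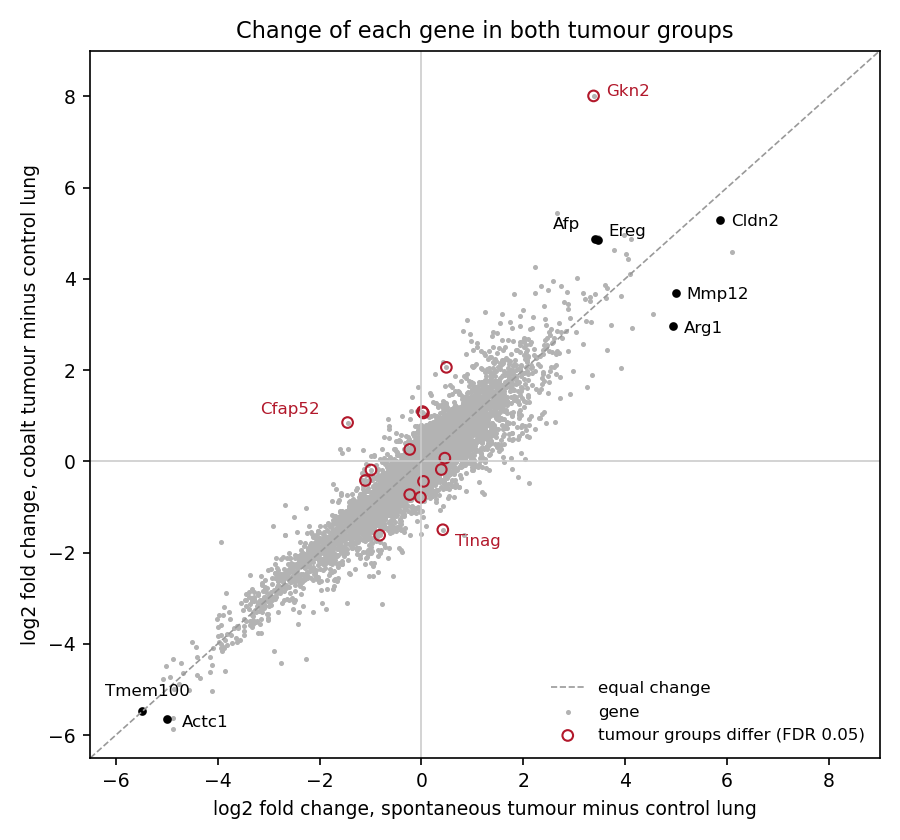
Log2 fold change of each of 18193 genes in spontaneous tumours (horizontal axis) and in cobalt tumours (vertical axis) against the same control lungs, with circles on the 15 genes called between the tumour groups and black points on 7 named genes. The changes correlated with r = 0.928 across genes, part of which comes from the shared controls.

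Changes against control lung were largely shared by the tumour groups. Across genes, which are not independent replicates, the log2 fold changes of both comparisons correlated with r = 0.928. Unchanged groups simulated against the same controls gave r = 0.26, and using 3 controls for one comparison and the other 3 for the second gave a mean of 0.891 (0.854 to 0.911 over 20 such divisions). The covariance was 0.526 against 0.0112 in the simulation, a difference of 0.515. Both comparisons called 2040 genes higher, against 438.1 for independent lists, and 2733 genes lower, against 639.4, while 1 gene was called in opposite directions. The simulation gave overlaps of 0 and 0.1, but it held no changed genes. It therefore cannot show how far shared controls raise the overlap. With the controls divided 3 and 3 the overlaps were 959.9 and 1624 on average, against 162.3 and 294.8 for independent lists. The fold changes had the same sign in 83.5% of genes, against 62.3% in the simulation. Tc2n (4.10 and 4.10 log2) and Tmem100 (-5.48 and -5.47 log2) are examples of equal change.

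The third comparison set cobalt tumours against spontaneous tumours directly. Few genes differed: limma called 8 genes higher and 7 lower of 18193 at a false discovery rate of 0.05, while 2105 genes had an unadjusted p under 0.05. The fit shares 1 spread per gene over all 18 arrays, controls included. For Gkn2 the SD was 0.41 in control lung, 2.57 in spontaneous and 0.62 in cobalt tumours, whereas neutrophil markers went the other way (1.86, 0.21 and 0.35). Where controls varied less than tumours, the p-values between tumour groups can be too small. Liph, a lipase that releases lysophosphatidic acid, was 2.09-fold higher in cobalt tumours (log2 10.51 ± 0.21 against 9.44 ± 0.25, SD, n = 6 each, limma adjusted p = 0.000836), with 6 of 6 cobalt tumours above all spontaneous tumours. Of the 13 genes named by rule it alone kept its call in all 18 fits that left out 1 array. The ciliary protein gene Cfap52 (4.93-fold, adjusted p = 0.0138), the neutral amino acid transporter Slc1a4 (2.97-fold, 0.0179), Rasgef1b (2.04-fold, 0.0288) and Tmem176b (1.4-fold, 0.0138) were also higher. So were Ppp1r32 and Lrrc10b, named after their values were seen (0.67 and 0.80 log2, adjusted p = 0.0191 and 0.038). Neither lay above control lung: the means of Ppp1r32 were 7.67 in control lung, 6.57 in spontaneous and 7.25 in cobalt tumours. Those of Lrrc10b were 8.36, 7.36 and 8.17. Gkn2 was 24.8-fold higher in cobalt tumours (14.19 ± 0.62 against 9.55 ± 2.57, 0.038), with 5 of 6 above all spontaneous tumours. With cobalt tumours near the highest value of the data, this fold may be too small as well. Tinag (3.79-fold, 0.038), the collagen Col6a3 (1.74-fold, 0.0288), the p53 target Phlda3 (1.7-fold, 0.038), the bile acid synthesis enzyme Hsd3b7 (1.48-fold, 0.0138), Rexo2 (1.42-fold, 0.0288), the dynactin subunit Dctn5 (1.39-fold, 0.0138) and Vps35l (1.31-fold, 0.0217) were lower in cobalt tumours.

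Most of these calls did not hold in every fit that left out 1 array, and for several of them leaving out a control was enough. Counts of higher and lower genes were 36 and 46 without cobalt tumour 6, 18 and 17 without spontaneous tumour 4, and 1 and 0 without cobalt tumour 1. They were 5 and 4 without control 2, 5 and 3 without control 3 and 4 and 2 without spontaneous tumour 5. The count of lower genes alone moved over 1.5-fold without control 4 (4), spontaneous tumour 1 (16) or cobalt tumours 3 (4), 4 (3) or 5 (19). Cfap52, Tmem176b, Hsd3b7 and Dctn5 missed the threshold without cobalt tumour 1 (adjusted p = 0.0573 each), and Slc1a4 and Vps35l without that tumour (0.0602 and 0.0665) or spontaneous tumour 5 (0.0581 and 0.0653). Rasgef1b missed it without control 2 or 3, spontaneous tumour 2 or 5 or cobalt tumour 1 (0.0502 to 0.0792), and Rexo2 without control 3, spontaneous tumour 3 or 5 or cobalt tumour 1, 3 or 4 (0.0502 to 0.0665). Col6a3 missed it without control 2, 3 or 4, spontaneous tumour 3 or 5 or cobalt tumour 1, 2, 3 or 4 (0.0502 to 0.0792). Phlda3 missed it without control 2, 3, 4, 5 or 6, spontaneous tumour 2, 5 or 6 or cobalt tumour 1, 2, 3 or 4 (0.0537 to 0.11). Gkn2 missed it without any 1 control, spontaneous tumour 2, 3 or 5 or cobalt tumour 1, 2, 3 or 4 (0.0563 to 0.114), and Tinag without any 1 control, spontaneous tumour 3, 4 or 5 or cobalt tumour 1, 2, 4 or 5 (0.0508 to 0.0792). Among the arrays with high Xist alone (6 controls, 2 spontaneous and 4 cobalt tumours) limma called 0 genes, and a fit of the 12 tumours alone called 1 gene, Liph.

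NRF2 targets did not differ detectably between cobalt and spontaneous tumours. None of the 30 passed the test (1 fell when adjusted over the list alone), and the median log2 difference was -0.11 (camera adjusted p = 0.324). Hmox1 (0.08 ± 0.27 log2, difference ± SE), Gclc (0.03 ± 0.20) and Nqo1 (0.30 ± 0.22) had limma adjusted p of 0.948, 0.979 and 0.65. In the arrays with high Xist alone the list's median was -0.31 (adjusted p = 0.00638). None of 28 antioxidant enzymes passed the test (median -0.09, adjusted p = 0.557). Of the 11 lists called by camera, the cell cycle list had the largest median difference, -0.81 (adjusted p = 9.03e-18, and 0.591 with an estimated correlation). No member passed over all genes, and 23 of 39 were lower when adjusted over the list alone. Cobalt tumours 4 and 6 lay below all spontaneous tumours on that list, and the other 4 lay within their range of 0.60 to 1.89 log2 above the control mean. Alveolar macrophage markers (-0.69, 3.58e-06, 5 of 21 lower when adjusted over the list alone), markers of other macrophages and monocytes (-0.54, 3.65e-06), interferon response genes (-0.41, 0.000105) and cytokines and chemokines (-0.33, 0.000942) were lower in cobalt tumours too. Their adjusted p was 0.591, 0.591, 0.842 and 0.842 with an estimated correlation. These 5 lists kept their call in all 18 fits that left out 1 array, but some of their medians moved. Without spontaneous tumour 2 they were -0.23 for interferon response genes and -0.18 for cytokines and chemokines (adjusted p = 0.0356 each), and without spontaneous tumour 1 -0.45 for alveolar macrophage markers. Cytokines and chemokines missed the threshold without the 6064 dimmest genes (-0.27, 0.247), and interferon response genes (-0.20, 0.337) and markers of other macrophages and monocytes (-0.18, 0.0623) in the arrays with high Xist alone. An exact permutation test of the list's mean per array, added after these results were seen, gave adjusted p of 0.0779 for markers of other macrophages and monocytes, where all 6 cobalt tumours lay below all spontaneous tumours, and 0.499 for the cell cycle. With 6 against 6 arrays the smallest p is 0.00216, so 1 fully separated list alone among 36 could not get below 0.0779. Fry called 0 of 36 lists. In each list other than the cell cycle and alveolar macrophages, at most 3 members rose or fell when adjusted over the list alone.

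**Figure D5:**
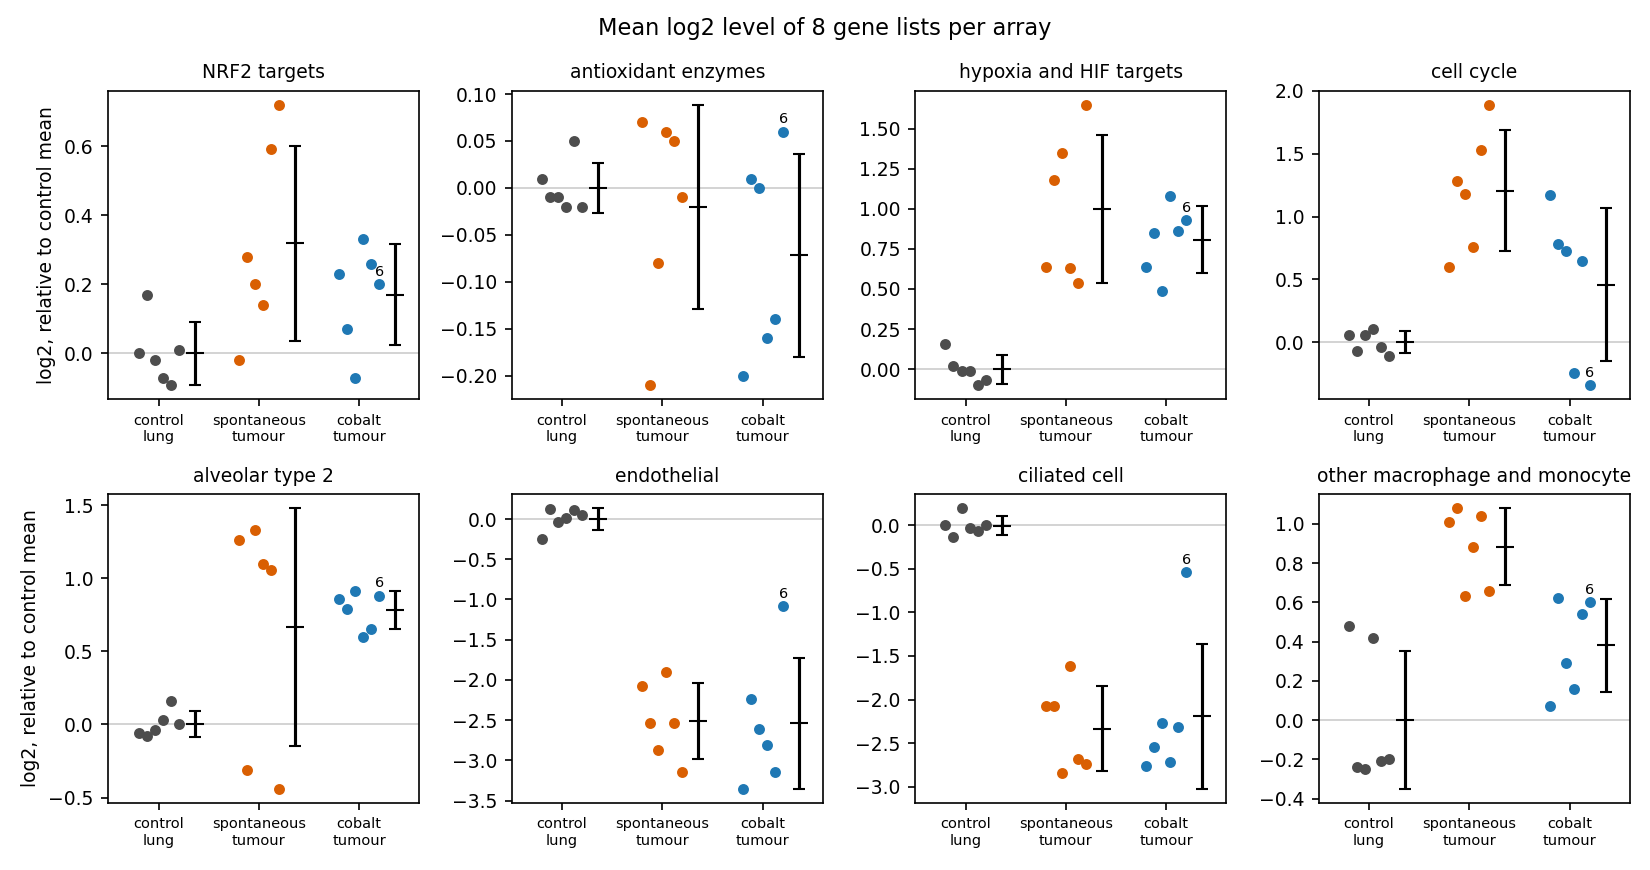
Mean log2 level of 8 gene lists on each array relative to the mean of the control lungs, with the bar and whiskers giving the mean and SD of 6 arrays and a 6 marking cobalt tumour 6. For the cell cycle list the spontaneous tumours lay at 0.60 to 1.89 and the cobalt tumours at -0.34 to 1.17.

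The other 6 lists called between the tumour groups each lost their call in at least 1 fit that left out 1 array, and none passed with an estimated correlation. B and plasma cell markers (median log2 difference -0.25, camera adjusted p = 0.00355) missed the threshold without spontaneous tumour 1 (0.0623), and p53 targets (-0.27, 0.02) without spontaneous tumour 2 (0.0742) or 4 (0.0708). With an estimated correlation the adjusted p of these 2 lists was 0.842 and 0.591. MAPK output (0.17, 0.0247) missed it without spontaneous tumour 1 or 5 or cobalt tumour 5 (0.0556 to 0.225), and alveolar type 2 markers (0.29, 0.0247) without spontaneous tumour 2 or 6 or cobalt tumour 6 (0.0609 to 0.707). For these 2 the adjusted p with an estimated correlation was 0.842 and 0.862. Club cell markers (-0.45, 0.0409) missed it without control 2, spontaneous tumour 1, 2, 4 or 5 or cobalt tumour 1 or 4 (0.0505 to 0.255). Mesenchymal transition regulators (-0.17, 0.0409) missed it without control 2, spontaneous tumour 1, 2, 4 or 6 or cobalt tumour 1, 3 or 5 (0.0505 to 0.229). For these 2 it was 0.842 each. Over the fits that left out 1 array the medians moved too. They ranged from 0.06 to 0.29 for MAPK output, 0.10 to 0.42 for alveolar type 2 markers and -0.33 to -0.15 for p53 targets. For club cell markers the range was -0.92 to -0.35, for mesenchymal transition regulators -0.27 to -0.07 and for B and plasma cell markers -0.36 to -0.19. Without the 6064 dimmest genes p53 targets (0.128), mesenchymal transition regulators (0.128) and club cell markers (0.0992) missed the threshold, and with array weights alveolar type 2 markers did (0.04, 0.724). In the arrays with high Xist alone the medians of MAPK output and club cell markers were -0.04 and 0.02, and that of antigen presentation genes was 0.37 (adjusted p = 0.0013). Of the lists not called, hypoxia and HIF targets (-0.18, 0.07) passed without spontaneous tumour 1, 4 or 5 or cobalt tumour 4 (0.00395 to 0.0172), and DNA repair (-0.10, 0.225) without spontaneous tumour 1 or cobalt tumour 1 or 3 (0.0406 to 0.0437). T and NK cell markers (-0.23, 0.0877) passed without spontaneous tumour 3 or 6 or cobalt tumour 5 (0.00887 to 0.0211) and antigen presentation (-0.08, 0.35) without spontaneous tumour 6 or cobalt tumour 5 (0.00446 and 0.0355). Other fits brought these medians nearer to 0 or past it, to -0.05 for hypoxia and -0.03 for DNA repair without spontaneous tumour 6, -0.01 for T and NK cells without spontaneous tumour 2 and 0.02 for antigen presentation without spontaneous tumour 1. Without cobalt tumour 6, endothelial markers (0.00, 0.962), fibroblast and matrix genes (0.01, 0.35), heart muscle genes (-0.13, 0.343) and ciliated markers (0.11, 0.116) had medians of -0.28, -0.35, -0.34 and -0.20 with adjusted p of 0.00256, 0.00877, 0.0042 and 0.0497. With array weights endothelial (-0.25, 0.00943) and heart muscle genes (-0.38, 0.00121) passed. With the level of Y-linked RNA as a covariate the fibroblast and matrix median was -0.38 (0.00196). Heart muscle genes also passed without spontaneous tumour 6 (0.042), with a median of -0.02 without spontaneous tumour 4, and fibroblast and matrix genes without spontaneous tumour 3 (0.0321). The unfolded protein list (-0.02, 0.557) passed without cobalt tumour 5 (0.037), and alveolar type 1 markers (0.15, 0.343) without cobalt tumour 1 (0.0212), with a median of -0.15 without cobalt tumour 6. Ciliated markers, with a positive median, passed without spontaneous tumour 1 or 4 or cobalt tumour 1, 2 or 4 (0.00327 to 0.0479).

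The remaining 13 lists were not called between the tumour groups and stayed so in all 18 fits that left out 1 array. Among pathway lists these were metal response (median log2 difference 0.00, adjusted p = 0.444), oxidase genes (-0.09, 0.255), lipid and sterol synthesis (-0.10, 0.907), gastric and gut epithelial genes (0.06, 0.343), injury-associated epithelial genes (-0.12, 0.343) and xenobiotic metabolism (-0.16, 0.962). Among cell types they were smooth muscle and pericytes (0.05, 0.907), mesothelium (-0.03, 0.907), neutrophils (-0.19, 0.825), dendritic cells, mast cells and eosinophils (-0.01, 0.557), red cells and platelets (0.02, 0.592), nerve, Schwann and neuroendocrine cells (0.03, 0.237) and adipocytes (0.04, 0.596). Of these, gastric and gut genes passed with array weights (0.17, 0.0474) and injury-associated genes in the arrays with high Xist alone (-0.39, 0.00266). Egfr, Mki67, Sftpc, Ager, Scgb1a1 and Nkx2-1 had limma adjusted p between 0.193 (Mki67, -1.29 log2) and 0.98 (Egfr). For 68 of 3548, 79 of 3546 and 0 of 5 called genes with several probe sets in the 3 comparisons, another probe set of the gene was called in the opposite direction, and none of the genes named here with a fold change was among them.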

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

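Among the tests in this part, those of sex and other numbers from the arrays with high Xist alone, the exact permutation of list means, the splits with all 18 arrays in the fit and the extension of the outlier search to list genes were chosen only after results were seen. A sample was listed here when its gap to the nearest other sample of its group, divided by the group's range, was above Dixon's 95% critical value, which chance gives in about 1 of 20 groups. Of 447 groups of 6 tested, over lists, named genes and array correlations, 45 met this against 22.4 expected by chance, in groups that are not independent because lists and genes share arrays, and 19 of the 45 were in cobalt tumour 6 and 7 in control 1.

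Cobalt tumour 6 lay close to the control lungs. Its mean r with its own group was 0.953, against 0.97 or more for the other cobalt tumours. A fit without this array gave 552 genes at least 2-fold higher in both tumour groups. In this array 84.2% of them lay above all 6 controls, which argues against a control lung under a tumour label. Single controls lay above all the other controls in 11.2% to 23.4% of these genes, where only 1 control can be the highest for a gene. The other cobalt tumours, at 95.3% to 98.4%, helped to choose these genes, so their shares were high by construction. Normal lung with the makeup of the control samples mixed into the tumour, as the whole cause, is argued against by control-like shares that ranged over 0.737, from 0.08 for heart muscle to 0.82 for alveolar type 1 genes. The share was 0.62 for fibroblast, 0.60 for ciliated, 0.38 for endothelial and 0.26 for smooth muscle genes. For the 552 genes higher in both tumour groups it was 0.65, so normal lung as a part of the cause stays open. Normal lung of another makeup, such as tissue without vein muscle, stays open, as does a tumour that keeps such genes.

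The control lungs held no array with low Xist and Y-linked RNA, whereas 6 of the 12 tumours did, and the labels give no sex per sample. Sex as the sole source of the calls against control lung is argued against by the arrays with high Xist alone, which called 62.5% of the genes called in spontaneous tumours and 77.1% of those called in cobalt tumours again in the same direction, with 2 spontaneous and 4 cobalt tumours. With the level of Y-linked RNA as a covariate, a fit fixed in advance, 69.4% of the calls in spontaneous and 87% of those in cobalt tumours were made again in the same direction. Which single genes differ by sex was not tested and stays open. The controls hold no low-Xist array, and low-Xist arrays were 4 of 6 in spontaneous and 2 of 6 in cobalt tumours. The tumour groups are therefore not balanced for them either. Of the 15 genes called between the tumour groups, 0 were called again with high Xist alone, with fewer arrays, and 14 with the Y-linked covariate. Sex as a source of those calls stays open.

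Cell cycle genes were lower in cobalt than in spontaneous tumours, with a median log2 difference of -0.81, but on the list's mean per array cobalt tumours 4 and 6 lay at -0.24 and -0.34 relative to the control mean and the other 4 at 0.65 to 1.17, within the 0.60 to 1.89 of the spontaneous tumours. That 1 tumour alone decides this is argued against by a median of -0.64 in the fit nearest to 0 among those without 1 array, but such fits cannot show whether cobalt tumours 4 and 6 together do, which stays open. The fit at -0.64 left out cobalt tumour 6, and because that value lay within the spread of these fits of the bound set for it, a part of the difference that comes from normal lung in that tumour cannot be told apart from the rest. The exact permutation p of the list's mean per array was 0.0498, under a bound written before this test was run but after the camera result was seen. That bound did not count the 36 lists tested, and over them the adjusted p was 0.499, where 1 separated list alone could get no lower than 0.0779, so chance stays open, and a lower rate of division in tumours of cobalt-exposed mice is a hypothesis these arrays do not settle.

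Other splits of the arrays bear on each count of called genes. A chance split is argued against for spontaneous tumours against controls, where 1 of 100 splits drawn, the real one, gave as many genes (6295, highest other 3). It is argued against for cobalt tumours against controls too, where again 1 of 100 did (6183, highest other 4383). That highest other split put cobalt tumour 6 with 5 controls, which points to a structure of the samples. These splits treat the arrays as independent samples, which the labels do not state. Chance cannot be excluded for cobalt against spontaneous tumours, where 6 of 100 splits gave at least the real 15 genes and the highest other gave 318, a split that put cobalt tumour 6 with 5 spontaneous tumours and points to the same structure. Fits of the 12 tumours alone, run first, gave 1 gene in the real split, 3 of 100 splits with as many and a highest other of 2, and were replaced because the counts reported come from all 18 arrays.

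The mean level of cobalt tumour 6 relative to control lung was -0.19 for xenobiotic metabolism, -0.54 for ciliated, -2 for heart muscle, -0.33 for B and plasma cell and -0.26 for adipocyte genes. Its log2 levels of Actc1 (9.02), Gpm6a (8.84), Hpgd (10.30), Mapt (9.04), Myh6 (8.07), Myl4 (7.54), Nqo1 (6.58), Ppbp (7.23), Ms4a1 (7.07), Lipe (9.03), Zeb1 (9.83) and Hamp (5.12) lay above the other cobalt tumours and that of Dusp4 (8.91) below them. Control 1 was apart on neutrophil genes (3.67 above the control mean) and oxidase genes (0.64), and in its log2 levels of Glrx (10.30), Slc40a1 (10.44), Kdm3a (9.43), Phlda3 (9.21) and Sod3 (10.82). Control 5 was apart on antioxidant (0.05) and mesenchymal transition (0.18) lists, control 3 on DNA repair (0.14) and in Kit (10.18) and Ms4a1 (11.39), and control 2 on adipocyte genes (1.16). Spontaneous tumour 2 was apart on cytokines (1.22), interferon response (0.50), T and NK cell markers (0.43) and Gstm1 (9.43). Spontaneous tumour 4 was apart on red cell and platelet markers (-0.24), Alas2 (9.29) and Tmem100 (9.99), spontaneous tumour 5 on the unfolded protein list (0.51), Mt2 (12.99) and Prdx3 (11.29), and spontaneous tumour 6 in Egfr (8.64) and Rrm2 (11.12). Cobalt tumour 5 was apart on the unfolded protein list (0.47). Of 10092 probe sets with several or no gene symbols, which enter no comparison, limma called 2095 in spontaneous and 2395 in cobalt tumours against control lung and 0 between the tumour groups, at a false discovery rate of 0.05.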

How the results depend on the processing

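Chosen only after the data were seen were the arrays with high Xist alone, control 1 and cobalt tumour 6 left out together, and the exact permutation of list means. Against control lung, counts of higher and lower genes stayed within 1.5 times under the settings for which they were tabulated, except all probe sets, which gave 6717 and 6778 in spontaneous and 6807 and 7074 in cobalt tumours because more features were tested. Between the tumour groups, genes higher (8) and lower (7) were 1 and 0 with only the 12 arrays, 0 and 0 with high Xist alone (fewer samples), 24 and 30 with control 1 and cobalt tumour 6 left out, and 0 and 0 by the exact permutation test, which recovered 0 simulated changes with 6 against 6 arrays. Lower genes were 14 without the 6064 dimmest genes, 12 with the mean of probe sets, 12 with array weights and 18 with the Y-linked covariate. Leaving out 1 array gave 1 (without cobalt tumour 1) to 36 (without cobalt tumour 6) higher and 0 to 46 lower. Titles share replicate numbers, but same-numbered arrays did not deviate together (r from -0.338 to 0.195, and no array correlated best with its own number), and the replicate block gave 1 and 0 genes. The NRF2 list in spontaneous tumours was 0.23 with cyclic loess, 0.35 without the dimmest genes and 0.35 with an estimated correlation (adjusted p = 0.161, 0.0678 and 0.351, the highest over its alternatives). In cobalt tumours it was 0.11 with fry (0.0477) and 0.07 to 0.16 without 1 array (0.0415 without cobalt tumour 3), and between the tumour groups -0.31 with high Xist alone. The antioxidant list in spontaneous tumours was -0.01 with cyclic loess, 0.12 with fry (0.0395) and -0.02 as an exact mean, and -0.07 as an exact mean in cobalt tumours, where a mean replaces the median. The correlation between the tumour groups was 0.903 with the Y-linked covariate, 0.897 with high Xist alone and 0.891 with 3 controls for each comparison, where genes higher in both were 959.9 on average (2040 with all controls) and genes lower in both 1624 (2733). Among lists called by camera in either setting, medians changed sign only between the tumour groups: with high Xist alone for MAPK output (-0.04), antigen presentation (0.37) and club cells (0.02), without 1 array for ciliated cells (-0.20 to 0.24, -0.20 without cobalt tumour 6), and for fibroblast and matrix genes with the Y-linked covariate (-0.38), without control 1 and cobalt tumour 6 (-0.35) and without 1 array (-0.35 without cobalt tumour 6, -0.25 without spontaneous tumour 3, up to 0.14), which camera already placed as lower at a median of 0.01. Endothelial markers, not called at a median of 0, were called at -0.28 without cobalt tumour 6 (0.00256) and at -0.25 with array weights (0.00943). Lists called in neither setting changed sign against control lung too, and with the mean of probe sets 1 gene called in spontaneous tumours and 6 in cobalt tumours were called in the opposite direction. Where no construction is named, the cause was not tested. Signal over background limits the dim genes, since no detection calls were used here.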

Other observations

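The genes in this part were chosen after their values were seen. Imprinted noncoding RNAs that share a chromosomal region, Meg3, Rian and Mirg, lay above all 6 controls in 11 of 12 tumours, and Dlk1, a paternally expressed gene of the same region, in 9 of 12. Meg3 was 3.62 log2 units above control lung in spontaneous tumours and 3.59 in cobalt tumours (limma adjusted p = 0.0107 and 0.0112), and Dlk1 4.02 and 4.55 (0.0339 and 0.0174). Spontaneous tumour 2 was an exception for all 4 RNAs, with Meg3 at 7.67 against 8 to 8.46 in controls. Metallothioneins Mt1 and Mt2, which bind metal ions, lay above all controls in 6 of 6 spontaneous tumours and in 4 and 3 of 6 cobalt tumours. Mt1 was 1.98 higher in spontaneous tumours and 0.79 higher in cobalt tumours than in control lung (adjusted p = 4.75e-05 and 0.041), while Mt2 was 2.11 higher in spontaneous tumours and differed by 0.53 in cobalt tumours (0.000157 and 0.264). The difference between the tumour groups was -1.19 for Mt1 and -1.58 for Mt2 and did not pass the test (0.126 and 0.0908).

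Hmga2, a chromatin protein of embryonic tissue, was at 11.41 and 11.09 in spontaneous tumours 2 and 6, the arrays that stood apart on the second principal component, and at 7.12 or less in the other 16 arrays (limma adjusted p = 0.0884 for spontaneous tumours against control lung). The genes with the largest positive loadings on that component were Anxa10, Krt20, Mcpt8, Dynap, Msln and Onecut2. Hnf4a, a transcription factor of liver and gut epithelium, was 2.51 higher in cobalt tumours than in control lung (adjusted p = 0.0028) and differed by 1.10 in spontaneous tumours (0.162), with a difference of 1.41 between the tumour groups that did not pass (0.348). The transcription factor Sox2 fell by 3.12 log2 units in cobalt tumours against control lung (0.00507), with cobalt tumour 6 at 9.34 and the other 5 at 4.11 to 5.97. Spontaneous tumours ranged from 5.33 to 9.84 for Sox2 and differed from control lung by -0.77 (limma adjusted p = 0.484). The Sox2 difference between the tumour groups, -2.35, did not pass the test (0.244). Gkn1, another gastrokine, was at 7.33 and 7.38 in cobalt tumours 2 and 4 and at 6.02 or less in the other 16 arrays, while Gkn2 lay above all controls in 6 of 6 cobalt and 5 of 6 spontaneous tumours.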
